A study of Ovis aries with 48 samples.

How the data were processed

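Small RNA was sequenced from adipose tissue of 16 female sheep born to mothers treated during gestation, giving 48 libraries. In the T cohort, 8 sheep gave 4 depots each (subcutaneous, visceral, epicardial and perirenal fat), 4 control sheep and 4 whose mothers had received testosterone propionate, 100 mg by intramuscular injection, from gestational day 30 to 90. In the BPA cohort, 8 other sheep gave subcutaneous and visceral fat, 4 control sheep and 4 whose mothers had received bisphenol A at 0.5 mg per kg per day by subcutaneous injection over the same days. Groups, depots and sheep numbers were taken from the labels, and each of the 12 groups held 4 libraries from 4 sheep. Libraries were made with a small RNA kit per the labels' protocols, and cutadapt 3.2, STAR 2.6.0c and featureCounts 1.6.1 are named in the submitters' processing notes. The genome build is not given in the sources used here.

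The deposited values are a signal that is never negative, reads per feature divided by a size factor per library, in 1 table per cohort for each of 4 RNA classes, 8 tables in all. The tables list 105 microRNAs, 694 snoRNAs, 1148 snRNAs and 2973 lncRNAs. Whole reads could be recovered from 100% of the values in every column, with a tolerance of 1e-05. The size factors recovered in this way equalled the median-of-ratios factors computed from the 8 libraries of a depot within each RNA class (SD of the log2 difference 0), so that the authors' scaling was set separately in each depot. For microRNAs of the T cohort, the deposited scale lay -0.83 log2 units from the cohort mean in visceral, -0.17 in subcutaneous, 0.35 in epicardial and 0.65 in perirenal libraries. Levels deposited for different depots were therefore not on a common scale. The comparisons of depots had been laid out on the deposited values, with rescaling beside them. After the scaling had been found, they were made instead on values rescaled by the median ratio over the libraries compared, and the scaling as deposited became the alternative. Comparisons of treatment within a depot, and of treatment effects between depots, used the values as deposited.

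Features with a mean value of at least 5 over the libraries of a comparison were tested. Values were taken as log2(value + 1) and fitted with limma 3.58.1 (R 4.3.3) with a trend of the spread with the mean, 1 fit per RNA class. Benjamini-Hochberg adjustment was made within each class, features with an adjusted p under 0.05 were called, and calls were summed over the 4 classes. A fold change on this scale understates the change of features of low level. Each depot of each cohort had its own fit of treatment, effects were compared between depots by the interaction in 1 fit per cohort, and each depot was compared with the mean of the other 3 in the control libraries of the T cohort. Visceral and subcutaneous fat were compared in the controls of each cohort. Fold changes of prenatal T and of BPA, which had separate controls, were correlated across features, with 100 permutations of the treatment labels. Features are not independent replicates, and this p rests on the permuted sheep.

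The depots of a cohort came from the same sheep, so that the labels pair their libraries. Deviations from the group means correlated with a median r of 0.17 between libraries of 1 sheep of the T cohort, over 0.1 in 27 of 48 pairs, and of -0.04 between different sheep. In the BPA cohort the medians were 0.18, with 5 of 8 pairs over 0.1, and -0.1. The library sets described below were not kept apart in these values. In the T cohort the highest r between different sheep (0.613) was between libraries of the later set. The lowest within 1 sheep (-0.479) was between a later and an early library. Fits with sheep as a block were made as alternatives. No pair of libraries of a group agreed within sampling noise: over 72 pairs the chi-square per degree of freedom lay between 14.1 and 1250, and every library was counted. No column was left out.

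Library numbers in the labels fell into 2 sets, up to 48 (early) and from 81 to 127 (later). Sets were unevenly spread over the groups. All 4 epicardial control libraries were of the later set, all 4 subcutaneous and all 4 perirenal libraries of prenatal T sheep were of the early set, and visceral libraries of the BPA cohort were early in 3 of 4 controls and 1 of 4 BPA sheep. Fits with a term for the set were made beside the others. Fits within 1 set were chosen after seeing the data. Each arm kept at least 2 libraries, except in a fit of a pair of snRNAs for BPA in visceral fat, which left 1 control and is not used.

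Lists of microRNAs, snoRNAs, snRNAs and lncRNAs were fixed before the data were examined and tested where at least 3 members passed the filter, with fry, with camera at a preset correlation of 0.01 and with camera at an estimated correlation, adjusted over the lists of a comparison. 6 microRNA lists could be tested: epithelium, pro-adipogenic, anti-adipogenic, inflammation, insulin and glucose, and the DLK1-DIO3 cluster, with 53 members of the latter in the tables. Some lists share members and are not independent results. Most anti-adipogenic members are let-7 microRNAs, all of which are also in the insulin and glucose list. MIR103, MIR107 and MIR143 are in that list and the pro-adipogenic one. MIR21 is in the pro-adipogenic and inflammation lists. The lists for striated muscle, blood cells and the vessel wall each had 1 member in the tables (MIR133, MIR150 and MIR143), the HOX cluster list had MIR10A and MIR10B, and the list for brown and beige fat had 0. The snoRNA, snRNA and lncRNA lists had 0 members by name, since the tables give those features by locus identifier. snoRNAs were therefore grouped by the gene they lie in, which was chosen after seeing the data: LOC105606646 in the DLK1-DIO3 region, ribosomal protein genes, translation factor genes, LOC114110053 and TEX14. Positions of genes relative to each other came from the RefSeq table of assembly ARS-UI_Ramb_v3.0, which held 105 of the microRNAs, 621 of the snoRNAs, 1010 of the snRNAs and 1404 of the lncRNAs. Its coordinates were not used.

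The features named were chosen by a rule laid down together with the lists. For each comparison and RNA class it took up to 3 features per direction with a symbol, and up to 1 with only a locus identifier, with the largest fold change among those called whose groups did not overlap. Where a class had none, it took the 2 with the smallest p, and for the interactions the 2 with the smallest p per class. Of each list it took up to 4 called members by p, or the member with the smallest p where the list test passed. The rule allowed no exceptions. 3 snRNAs are named outside it and marked where they appear. MIR133, MIR150 and MIR143, markers of other cell types fixed with the lists, are also given outside it as shares of microRNA reads. The shares of MIR133 and MIR150 were not tested between groups.

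Alternatives were pseudocounts of 0.5 and 5, no filter and a mean of at least 20, scaling to equal reads per table (CPM), the set term, the block, adjustment over the 4 tables together, 1 fit over all depots of a cohort, control and treated libraries together, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, and leaving out each sheep, with all of its libraries in the comparison. The fits were tested on simulated counts with 200 changed features. With so many changed, the adjusted p passes more easily than where few features change. The shares recovered therefore overstate what would be recovered of a few changed features. Of features changed 2-fold and 4-fold, 27.7% and 86.7% were recovered for prenatal T in subcutaneous fat (393 features), 8.7% and 61.8% in visceral (400 features), 30.9% and 80.9% in epicardial (425 features) and 13.3% and 39.5% in perirenal fat (457 features). For BPA the shares were 29.5% and 91.1% in subcutaneous (477 features) and 45.7% and 83.9% in visceral fat (432 features). For the interaction, the changes were placed only in visceral libraries of treated sheep. It recovered 1% and 23.4% for prenatal T (439 features) and 7.2% and 35.8% for BPA (470 features). The comparison of epicardial with the other depots recovered 46.2% and 87.8% (419 features).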

Results

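Small RNAs were measured in 4 adipose depots of control and prenatally testosterone-treated (prenatal T) female sheep and in 2 depots of control and prenatally bisphenol A-treated (BPA) female sheep, with 4 sheep in each group. The 48 libraries held between 260804 and 1742991 recovered reads in the 4 RNA classes (median 713221.5). MicroRNAs made up 83.8% to 92.8% of these reads, lncRNAs 5.99% to 14.1%, snoRNAs 0.277% to 3% and snRNAs 0.0595% to 0.927%. Let-7 microRNAs, a family abundant in differentiated tissue, accounted for 25% to 72.2% of microRNA reads. The snoRNA share also followed the library set. In each of the 8 groups that held both sets, every library of the later set had a higher share than every library of the early set (mean difference 1.22 percentage points, exact permutation p = 6.78e-06). The test takes the libraries of 1 sheep as independent.

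**Figure D1:**
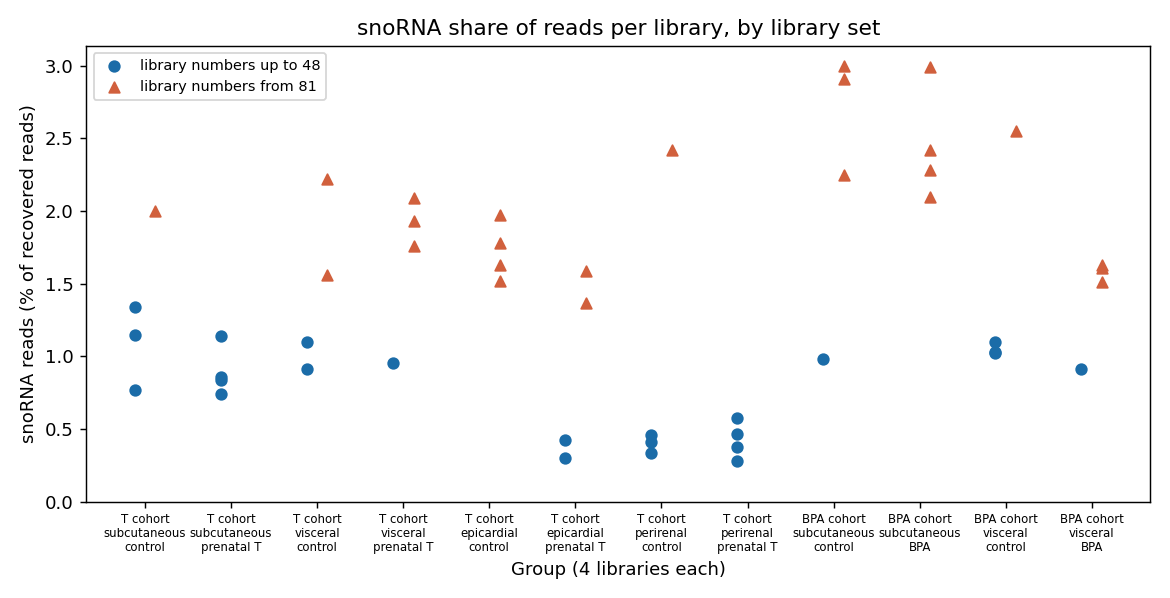
Share of snoRNA reads (% of recovered reads) in each of the 48 libraries, by group, with circles for library numbers up to 48 and triangles for numbers from 81. In each of the 8 groups holding both sets the triangles lie above the circles, with a mean difference of 1.22 percentage points.

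Epicardial fat of the control sheep was compared with their other depots. MicroRNAs that lie in HOX genes, which pattern the body axis, were low there: MIR10A, in HOXB3, had a log2 fold change of -3.86 (SE 0.33, adjusted p = 1.68e-08) and normalised reads of 199.7 ± 58.4 against 3190.0 ± 1701 (mean ± SD, n = 4 epicardial libraries and 12 of the other depots), and MIR10B, in HOXD4, one of -3.17 (SE 0.33, adjusted p = 2.04e-07). MicroRNAs of the DLK1-DIO3 cluster, an imprinted region, were high: 15 of 29 measured members rose and 0 fell, 18 when adjusted over the list alone, with a median of 0.92. Among them MIR127 had a fold change of 1.63 (SE 0.27, adjusted p = 0.00012), MIR323A one of 2.07 (SE 0.41, adjusted p = 0.00078) and MIR370 one of 1.86 (SE 0.37, adjusted p = 0.00078). The list passed with fry (adjusted p = 4.41e-05) and with camera at an estimated correlation (adjusted p = 0.00058).

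RNAs of other classes from the same region were also high in epicardial fat. All 7 measured snoRNAs lying in LOC105606646, a lncRNA gene that spans most of the cluster, rose, with a median of 2.52 (fry adjusted p = 7.99e-05, camera adjusted p = 0.114 with an estimated correlation). This group was chosen after seeing the data. The snoRNA LOC114109215 had a log2 fold change of 4.37 (SE 0.74, adjusted p = 0.00162). The lncRNA LOC105606646 itself had 1.90 (SE 0.30, adjusted p = 0.000886), although it overlaps the microRNAs and snoRNAs and its reads could not be told apart from theirs. MIR143, a microRNA of smooth muscle, fell (-1.56, SE 0.31, adjusted p = 0.00078; -0.92 with the set term), and the snoRNA LOC114113393 in EEF1B2 fell (-1.39, SE 0.26, adjusted p = 0.00269). MIR133, a microRNA of striated muscle, made up 3200 ± 2190 CPM of microRNA reads in epicardial control libraries (SD, n = 4), against group means from 199 to 998 in every other depot. Single control libraries of the cohort overlapped, with 1300 to 6330 in epicardial fat and up to 2570 in the other 3 depots. MIR150, a microRNA of lymphocytes, was at 6700 to 8140 CPM of microRNA reads in epicardial control libraries and at 1280 to 6550 in those of the other 3 depots of the cohort. In controls of the BPA cohort it was at 3530 to 11700 in subcutaneous and 4410 to 5140 in visceral fat.

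Other microRNA lists were lower in epicardial fat with fry on the common scale, namely anti-adipogenic (4 of 9 fell, MIRLET7F -0.88, MIR221 -0.89, adjusted p = 0.00197), insulin and glucose (7 of 13 fell, MIR103 -0.85, adjusted p = 0.000403) and inflammation (0 of 4 fell, MIR21 -0.64, adjusted p = 0.00918). The anti-adipogenic and the insulin and glucose lists share their let-7 members, so that they are not independent results. With camera at an estimated correlation the adjusted p was 0.158, 0.106 and 0.344. Scaled to equal reads per library (CPM), the fry adjusted p was 0.413, 0.413 and 0.442, and the median of the inflammation list turned from -0.39 to 0.14. On the scaling as deposited it was 0.199, 0.0443 and 0.85, and the examples named lost their calls on both scalings except MIR21, which had none. Of 11 pro-adipogenic members 3 fell (fry adjusted p = 0.0556), and 0 of 3 epithelial members were called (0.367, against 0.00276 with CPM and 0.026 on the scaling as deposited, higher).

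In all, limma called 96 of 423 features in epicardial fat, 61 higher and 35 lower, with 79 and 19 on the scaling as deposited and 73 and 33 with CPM. All 4 epicardial control libraries were of the later set, and with a term for the set 42 features were called (23 higher, 19 lower), 28 of them shared. The count was 43 without sheep 131, 37 without 132 and 53 without 201. Within control groups holding both sets, the MIR143 share of microRNA reads was lower in the later set (mean difference -3.78 percentage points, exact permutation p = 0.000651), and the DLK1-DIO3 share was higher (0.287 percentage points, exact permutation p = 0.00977). Both tests take the libraries of 1 sheep as independent. In such groups of the T cohort, all later libraries were of sheep 098 or 201, and sheep 131 and 132 were early. With the set term MIR10A had a log2 fold change of -3.17, the DLK1-DIO3 microRNAs a median of 0.78 (fry adjusted p = 0.000196) and the snoRNAs of LOC105606646 a median of 1.98 (fry adjusted p = 0.0015).

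**Figure D2:**
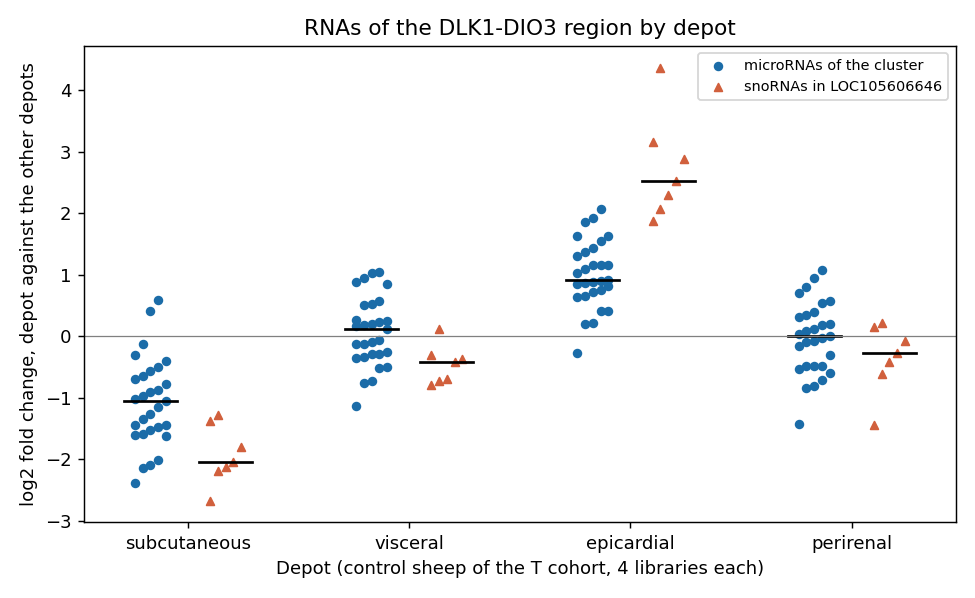
Log2 fold change of each depot against the mean of the other 3 in control sheep of the T cohort (y axis, 4 libraries per depot), with circles for microRNAs of the DLK1-DIO3 cluster, triangles for snoRNAs lying in LOC105606646 and bars for medians. Medians were 0.92 and 2.52 in epicardial and -1.05 and -2.05 in subcutaneous fat.

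Subcutaneous fat showed the opposite levels of the DLK1-DIO3 cluster. It was compared within the same control libraries as epicardial fat, so that this is not an independent result. Of 29 microRNAs 19 fell and 0 rose, 20 when adjusted over the list alone, with a median of -1.05. MIR369 had a log2 fold change of -2.38 (SE 0.39, adjusted p = 0.000121), MIR543 one of -2.10 (SE 0.38, adjusted p = 0.000219) and MIR382 one of -1.62 (SE 0.26, adjusted p = 0.000112). The list passed with fry (adjusted p = 3.08e-05) and with camera at an estimated correlation (adjusted p = 0.00252). Of the 7 snoRNAs in LOC105606646, 3 fell, with a median of -2.05 (fry adjusted p = 0.00122, camera adjusted p = 0.0442 with an estimated correlation). LOC114109206 among them was at 0.328 ± 0.657 against 11.1 ± 12.6 normalised reads. Of the 4 subcutaneous control libraries 3 were early, and the sets may add to this fall. The DLK1-DIO3 share of microRNA reads was 0.36% to 0.369% in the early ones and 0.668% in the later one (sheep 201). In control libraries of the other depots of the cohort it was 0.462% to 1.15% in the early set. It was 0.731% to 3.77% in the later set.

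MicroRNAs higher in subcutaneous fat included MIR221 (1.80, SE 0.23, adjusted p = 1.23e-05), MIR23A (1.40, SE 0.24, adjusted p = 0.000131), MIR17 (1.27, SE 0.31, adjusted p = 0.00246) and MIR103 (1.24, SE 0.21, adjusted p = 0.000131). MIR200B, an epithelial microRNA, was lower (-2.96, SE 0.65, adjusted p = 0.00103). The snoRNA LOC114115930 in RPL4 and the lncRNA LOC101111367 were higher, by 1.34 and 2.31. With fry the pro-adipogenic list (4 of 11 rose), the anti-adipogenic list (2 of 9) and the inflammation list (1 of 4) were higher, each with an adjusted p of 0.0294, and each had an adjusted p of 0.368 with an estimated correlation. On the scaling as deposited their fry adjusted p was 0.165, 0.256 and 0.251. The epithelial list was lower (1 of 3 fell, fry adjusted p = 0.0294, adjusted p = 0.542 with an estimated correlation), and of 13 insulin and glucose members 3 rose (fry adjusted p = 0.101). In all 61 of 423 features were called, 29 higher and 32 lower, with 28 and 44 on the scaling as deposited and 14 and 46 with CPM. Without sheep 132 the count was 28.

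Perirenal fat was high in MIR10B (2.86, SE 0.33, adjusted p = 2.17e-06, 10333 ± 4586 against 2239.6 ± 2489 normalised reads) and MIR143 (1.87, SE 0.31, adjusted p = 0.000292). The MIR143 share of microRNA reads was 3.72% in the later library of the group (sheep 098) and 9.88% to 15.3% in the 3 early ones, and with the set term the fold change was 1.55. The let-7 member MIRLET7F rose by 1.34, and MIR29B-1 and MIR29B-2, which had identical values and are counted separately in the table, by 1.28. MIR221 fell (-1.22, SE 0.23, adjusted p = 0.00091). The lncRNA LOC105612888 rose (2.68, SE 0.45, adjusted p = 0.000992), LOC114114532 fell (-1.45, SE 0.29, adjusted p = 0.0025) and the snoRNA LOC114117362 fell (-1.43, SE 0.29, adjusted p = 0.0125). Of 29 DLK1-DIO3 microRNAs 2 fell, MIR380 (-1.43) and MIR127 (-0.84), and MIR127 had a fold change of 0.04 on the scaling as deposited. The list had a median of 0.01, and on the scaling as deposited one of 0.79 (fry adjusted p = 0.00018). No list passed with fry, and the adjusted p was 0.177 for insulin and glucose (4 of 13 rose), 0.306 for inflammation, 0.717 for epithelium and 0.773 for each of the 3 others. In all 48 of 423 features were called, 25 higher and 23 lower, with 96 and 14 on the scaling as deposited and 32 and 12 with CPM. Without all 4 libraries of sheep 098 the count was 47 higher and 56 lower. The total was 19 without 131, 21 without 132 and 13 without 201.

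Visceral fat had few features apart from the mean of the other depots. MIR200B was higher (2.51, SE 0.65, adjusted p = 0.0322) and MIR10B lower (-1.33, SE 0.33, adjusted p = 0.0322). The lncRNA LOC114118460 was higher (2.31, SE 0.56, adjusted p = 0.0338) and LOC101105119 lower (-2.56, SE 0.58, adjusted p = 0.0338). The groups overlapped for each of them. In all 6 of 423 features were called, 3 higher and 3 lower, with 1 and 62 on the scaling as deposited and 1 and 2 with CPM. Leaving out any of the 4 sheep left 0 to 3 calls, and with the set term there were 17. No list passed with fry, with an adjusted p of 0.105 for epithelium, 0.259 for the anti-adipogenic and inflammation lists, 0.327 for pro-adipogenic and 0.516 for the 2 others. The DLK1-DIO3 list had a median of 0.12, and on the scaling as deposited one of -0.94 (fry adjusted p = 2.03e-05).

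**Figure D3:**
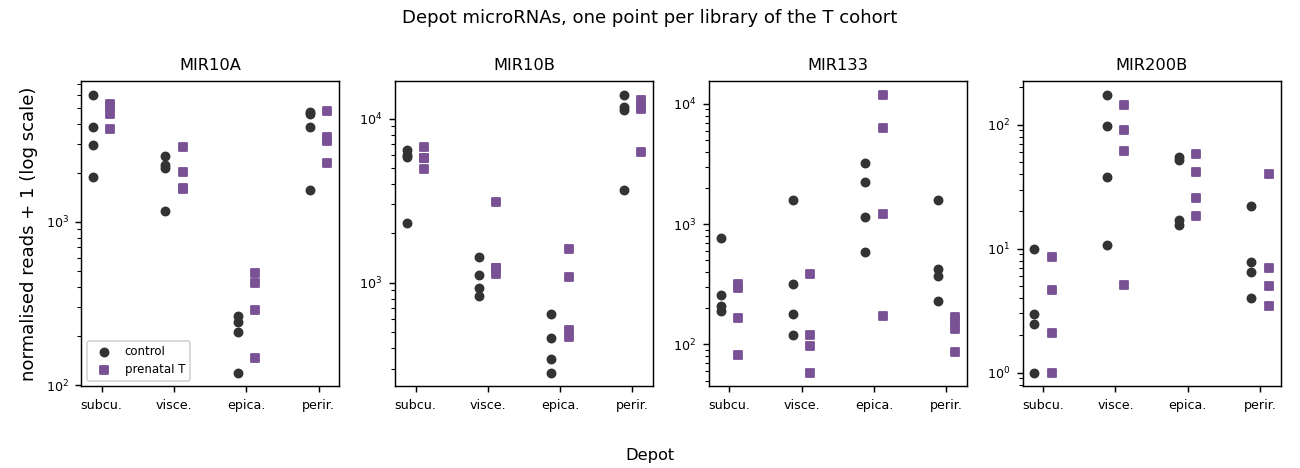
Normalised reads + 1 on a common scale (y axis, log scale) of 4 microRNAs in the 32 libraries of the T cohort, by depot, with circles for control and squares for prenatal T sheep, 4 each. MIR10A and MIR10B are lowest in epicardial fat, and MIR10B had a mean log2 fold change of 2.86 in perirenal fat of controls.

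Visceral and subcutaneous fat of control sheep were compared directly in both cohorts. In visceral fat MIR200B was higher by 3.85 in the T cohort and 4.07 in the BPA cohort (adjusted p = 0.00368 and 4.61e-06), and MIR218A, which lies in SLIT3, by 2.13 and 2.13 (adjusted p = 0.00368 and 0.0015). MIR10B was lower (-2.27 and -1.70), as was MIR17 (-1.49 and -1.18). MIR21, a microRNA of inflammatory signalling, was lower in the BPA cohort (-2.29, SE 0.33, adjusted p = 7.85e-05). In the DLK1-DIO3 cluster 10 of 22 microRNAs rose and 0 fell in the T cohort (fry adjusted p = 0.034, adjusted p = 0.121 with an estimated correlation), among them MIR543 (1.94), MIR432 (1.77) and MIR433 (1.92). On the scaling as deposited the fry adjusted p was 0.247. In the BPA cohort 7 of 24 rose and 0 fell (fry adjusted p = 0.0677), among them MIR432 (1.72) and MIR433 (1.64). The epithelial list was higher in the BPA cohort, with 2 of 4 members (MIR200A adjusted p = 0.00284, fry adjusted p = 0.0417, adjusted p = 0.454 with an estimated correlation), and had a fry adjusted p of 0.0903 in the T cohort. Of 11 pro-adipogenic members 2 fell in each cohort (fry adjusted p = 0.0903 and 0.0677), and on the scaling as deposited the adjusted p was 0.00306 and 0.00596.

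Other classes gave fewer calls. The snRNA LOC114117093 was higher in visceral fat of both cohorts, by 1.16 and 1.52. In the T cohort it did not pass with the set term or edgeR, and in the BPA cohort not with control and treated libraries together. The lncRNA LOC101111367 was lower in the T cohort (-3.01), and LOC114113790 was higher in the BPA cohort (2.33). In all 31 of 384 features were called in the T cohort (16 higher, 15 lower), 59 with sheep as a block, 40 with the set term and 12 within the early set alone, and 11 higher and 41 lower on the scaling as deposited. In the BPA cohort 37 of 452 were called (20 higher, 17 lower), 67 with the set term, with 18 and 98 on the scaling as deposited and 45 and 14 with CPM. The T count was 4 without sheep 098 and the BPA count 12 without sheep 924.

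Prenatal T was compared with control in each depot, to ask whether it alters small RNAs of fat. In epicardial fat 3 features were called, each an snRNA that was higher relative to its class, within which values were scaled. The share of all snRNAs was 0.0595% to 0.209% of reads in prenatal T sheep and 0.161% to 0.395% in controls. LOC114115462 had a log2 fold change of 0.97 (SE 0.28, adjusted p = 0.0191) and normalised reads of 46.1 ± 14.4 against 23.6 ± 8.58 (n = 4 and 4). LOC114111395 and LOC114111412, named after their values were seen, each rose by 0.84 (adjusted p = 0.0298) and had an r of 1 with each other over the 32 libraries, with ratios of their values from 0.85 to 1. MIR150 was at 2436 ± 585 against 4801 ± 1266 (-0.98, SE 0.25, adjusted p = 0.0948) and MIR485 of the DLK1-DIO3 cluster at -1.16 (adjusted p = 0.0948), neither called. The pro-adipogenic list was higher with fry, with positive values in 10 of 11 members, 0 of them called (MIR148A 0.88, SE 0.34, adjusted p = 0.158, list adjusted p = 0.00503). Its adjusted p was 0.36 with an estimated correlation and 0.297 with CPM. All 4 controls were of the later set, as were 2 of the 4 prenatal T libraries. For 1 member, MIR143, the share of microRNA reads was 9.12% and 7.32% in the early prenatal T libraries. It was 2.64% and 2.39% in the later ones and 1.39% to 2.65% in controls. MIR133 ran from 372 to 25900 CPM of microRNA reads in the 4 epicardial libraries of prenatal T sheep and from 1300 to 6330 in controls. Unadjusted, 69 features had a p under 0.05 (21.6 expected by chance). With the set term, within the later set alone and with edgeR there were 0 calls, and with DESeq2 17, of which 0 were among the 3. Without 1 of 5 of the 8 libraries (controls 098, 131 and 201, prenatal T 185 and 255) there were 0, without control 132 there was 1 and without prenatal T 233 there were 8.

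Of the other depots, 0 of 407 features were called with limma in subcutaneous fat (12 with an unadjusted p under 0.05, 2 with edgeR, 0 with DESeq2), 0 of 410 in visceral fat (29, 4 and 6, and 7 with the set term) and 0 of 471 in perirenal fat (12, 0 and 1). The smallest p in subcutaneous fat were those of MIR3959 (1.28, SE 0.30, adjusted p = 0.0535, 18.7 ± 2.15 against 7.29 ± 2.28 normalised reads) and MIR369 (1.55, SE 0.38, adjusted p = 0.0535), both of the DLK1-DIO3 cluster, of which 2 of 24 passed when adjusted over the list alone. In visceral fat MIR3955 had 2.03 (SE 0.52, adjusted p = 0.192) and the snoRNA LOC114117654 in KIAA1217 3.24 (SE 0.84, adjusted p = 0.134). In perirenal fat MIR133 had -1.95 (SE 0.54, adjusted p = 0.368), at 209 ± 64.8 against 1039 ± 1002 normalised reads, and was called by DESeq2. The DLK1-DIO3 list was higher at the preset correlation of camera in subcutaneous (adjusted p = 0.0344), visceral (0.0179) and perirenal fat (1.05e-06), but the adjusted p was 0.422, 0.392 and 0.343 with an estimated correlation and 0.657, 0.727 and 0.33 with fry. The subcutaneous list had a median of -0.01 and a mean of 0.1. The anti-adipogenic and the insulin and glucose lists share their let-7 members. Both were lower at the preset correlation of camera in visceral (0.0179 and 0.0352) and perirenal fat (0.00911 and 0.00667). With an estimated correlation the adjusted p was 0.247 for each in visceral and 0.356 for each in perirenal fat. A difference of treatment effects between depots was called for 0 of 441 features with limma (20 with an unadjusted p under 0.05), 0 with edgeR and 0 with DESeq2. The limma test recovered 1% of 2-fold and 23.4% of 4-fold changes in simulated counts, so that most such differences would not be called. The smallest adjusted p was 0.589, for the lncRNAs LOC105616014 and LOC101111367.

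BPA was compared with control in subcutaneous and visceral fat. In visceral fat 2 of 437 features were called, the snRNAs LOC114117060 (-1.16, SE 0.33, adjusted p = 0.00901, 119.8 ± 29 against 271 ± 78.8 normalised reads) and LOC114117093 (log2 fold change -1.15, SE 0.29, adjusted p = 0.00355). The second was named after its values were seen. The pair had an r of 0.97 with each other over the 16 libraries. Subcutaneous values for the pair were 0.57 and 0.72 (adjusted p = 0.236 and 0.107), and the difference of the effects, visceral minus subcutaneous, was -1.73 (SE 0.38, adjusted p = 0.000132) and -1.87 (SE 0.34, adjusted p = 3.64e-06), the only 2 called of 470 features. With the set term the effect in visceral fat was -0.95 and -0.98 (adjusted p = 0.207 and 0.145) and the difference of effects -1.69 and -1.84 (adjusted p = 0.000608 and 2.23e-05). The share of all snRNAs was also lower in visceral fat of BPA sheep, at 0.155% to 0.251% of reads against 0.291% to 0.702% in controls, and in subcutaneous fat it was 0.431% ± 0.189 against 0.252% ± 0.0981 (mean ± SD, n = 4 each). MIR150 was at 2540 to 3930 CPM of microRNA reads in visceral fat of BPA sheep and at 4410 to 5140 in controls. In subcutaneous fat the ranges overlapped, at 2850 to 3910 and 3530 to 11700. With limma 0 of 76 microRNAs were called for BPA in visceral fat (smallest adjusted p = 0.688). On the deposited values 1 of them had groups without overlap (1.32%, with 2.86% expected by chance). Visceral controls were early in 3 of 4 libraries and BPA libraries in 1 of 4. Without the visceral library of BPA sheep 918 there were 23 calls and without control 908 there was 1.

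**Figure D4:**
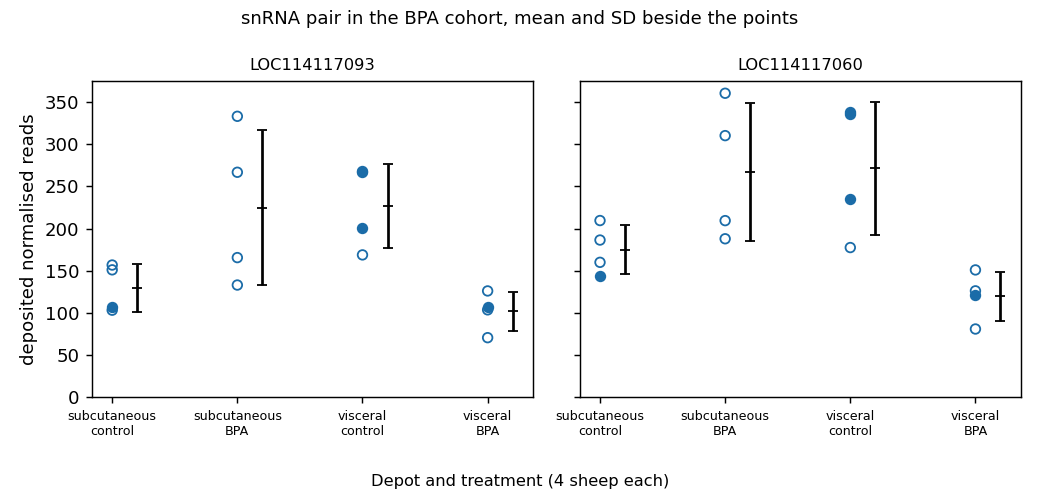
Deposited normalised reads (y axis) of the snRNAs LOC114117093 and LOC114117060 in the 16 libraries of the BPA cohort by depot and treatment, with filled points for the early and open points for the later library set, and the mean and SD (n = 4) beside them. The difference of BPA effects between depots was -1.87 and -1.73 on the log2 scale.

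In subcutaneous fat 0 of 477 features were called with limma (25 with an unadjusted p under 0.05, 3 with edgeR, 0 with DESeq2), and without BPA sheep 977 there were 5. MIRLET7B had 0.74 (SE 0.24, adjusted p = 0.511) and MIR26B -0.48 (SE 0.17, adjusted p = 0.511). In visceral fat MIR370 and MIR493, of the DLK1-DIO3 cluster, had 0.81 and 0.67 (adjusted p = 0.688 for both). The DLK1-DIO3 list was lower in subcutaneous and higher in visceral fat at the preset correlation (adjusted p = 2.35e-05 and 0.00182), but the adjusted p was 0.279 and 0.402 with an estimated correlation and 0.398 and 0.842 with fry. The anti-adipogenic and the insulin and glucose lists, which share their let-7 members, were higher in subcutaneous fat at the preset correlation of camera (0.036 each). With an estimated correlation the adjusted p was 0.287 and 0.279.

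The effects of prenatal T and BPA were compared across features. The fold changes had an r of -0.332 (rho -0.244) over 395 features in subcutaneous fat and 0.289 (rho 0.306) over 390 in visceral fat. Among permuted labels r ran from -0.494 to 0.53 and from -0.614 to 0.659, with a permutation p of 0.43 and 0.32. With the set term r was 0.023 and 0.076.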

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

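The tests of explanations below were all written down after their results had been seen. Counts over other splits of the libraries, with their threshold of 5% of the splits, had been laid down beforehand.

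The snoRNA share of reads lay higher in the later library set in every group holding both. Sets were compared within groups of 1 treatment, so that prenatal treatment cannot give this difference; that in controls alone (5 groups, mean difference 1.41 percentage points, exact permutation p = 0.000651) is part of the same separation, not a further test. Within group and set the share had an r of -0.238 with depth (permutation p = 0.14), so that a part for depth stays open. In 26 of 26 pairs of an early and a later library of a group the later had the higher share. It was the deeper of the pair in 11 of them, which argues against depth as the whole cause. The sets differed in share with an exact permutation p = 6.78e-06, which is the pattern itself and cannot tell what sets them apart. A difference in how the sets were prepared or sequenced may be the cause. That was not tested, nor was any biological explanation apart from treatment. The permutation between sets takes the libraries of 1 sheep as independent.

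The difference of BPA effects on LOC114117093 between visceral and subcutaneous fat was -1.87, and on LOC114117060 it was -1.73. Both stood out because the test of the difference itself passed. The library set as the whole cause is argued against by the difference of -1.84 that LOC114117093 had with the set as a term. The pair had an r of 0.97 with each other, with ratios from 1.05 to 1.55, which both shared reads and shared regulation would give, and this stays open since their sequences were not compared. Of the other splits of the sheep, 3 of 35 gave as many calls, the real one included (real count 2, highest other 6, for controls of 902, 908, 910 and 918), so that chance was not excluded. Values were scaled within the snRNA class, which takes out a shift shared by the whole class. Over both depots the snRNA share differed by -0.146 percentage points within depot and set (exact permutation p = 0.191). A mean over both depots cannot show a shift of opposite sign in them. The group means with BPA and in controls were 0.203% and 0.415% in visceral and 0.431% and 0.252% in subcutaneous fat. An effect of BPA on these snRNAs that depends on the depot stays open, as does a change of cell types, which was not tested for this pair.

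The let-7 share of microRNA reads varied widely within groups. The ranks of the sheep over the 4 depots had a Kendall's W of 0.461 (permutation p = 0.052), and sheep 255 was at 35.1% in visceral and 25% in perirenal fat. The library set may contribute (later minus early 11 percentage points, exact permutation p = 0.00112), in a test that also takes the libraries of 1 sheep as independent. Sheep means were 47.8% ± 9.2 for prenatal T and 58% ± 5.8 for controls (SD, n = 4 each, exact permutation p = 0.114). Within depot and library set, prenatal T libraries were lower than controls by a mean difference of -10.9 percentage points (exact permutation p = 0.023), a test that takes the libraries of 1 sheep as independent. The effects of animal and treatment stay open.

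Of the 7 library measures compared in this way in each cohort, unadjusted and with the same limit, 3 others had small p. In prenatal T libraries the lncRNA share differed by -1.87 percentage points (exact permutation p = 0.0239) and the microRNA share by 2.03 (exact permutation p = 0.0139). These 2 classes make up most of the reads, so that their shares are not separate results. Among prenatal T sheep, sheep 255 had the lowest lncRNA share in each depot. It was 5.99% in visceral, 6.88% in perirenal, 9.16% in epicardial and 11% in subcutaneous fat. In BPA libraries the snoRNA share differed by -0.458 percentage points (exact permutation p = 0.0232), so that a smaller difference of this share with BPA, apart from that between sets, stays open.

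Splits of the 8 sheep with at least as many calls as the real split numbered 2 of 35 for prenatal T in epicardial fat (real 3, highest other 5) and 4 of 35 for BPA in visceral fat (2 and 78), so that chance was not excluded for either. The split with 78 calls, sheep 902, 910, 977 and 984 against the others, is that of the later against the early library set, and with the set as a term there were 0 calls for BPA. Where the real split had 0 calls, every split had as many and the count decides nothing: 35 of 35 for prenatal T in subcutaneous (highest other 25), visceral (24) and perirenal fat (4) and for its effect by depot (2), and 35 of 35 for BPA in subcutaneous fat (15).

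For depots, splits were drawn by shuffling the depots within each sheep, so that every sheep kept 1 library per depot. For subcutaneous fat against the others, 1 of 100 splits had as many calls (61 and 20), a share under 5%. The share was also under 5% for epicardial (1 of 100, 96 and 72) and perirenal fat (2 of 100, 48 and 64). It was not under 5% for visceral fat (5 of 100, 6 and 25). A shuffled split of perirenal fat gave more calls (64) than the real one (48). Shares were not adjusted over the depots and do not by themselves exclude chance. Every epicardial control library was of the later set, which shuffling breaks up, so that the epicardial share cannot tell depot from set. For visceral against subcutaneous fat, 1 of 35 splits had as many calls in the T cohort (31 and 25) and 2 of 35 in the BPA cohort (37 and 66, the latter with both libraries of sheep 902 on 1 side). The splits that part every pair of libraries of a sheep, as the real one does, are too few for a share under 5%, and among the 7 others the highest counts were 0 and 2.

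Single libraries stood apart from the 3 others of their group in 10 of 84 groups of library measures (4.2 expected by chance) and 31 of 397 groups of named features (19.9 expected by chance). Some were the only library of their set in the group. In the T cohort these were perirenal control 098, subcutaneous control 201 and visceral prenatal T sheep 255. In visceral fat of the BPA cohort they were control 902 and BPA sheep 918. For them the set and the animal cannot be told apart. In perirenal controls, sheep 098 had 283000 reads (others from 1160000), a snoRNA share of 2.42% (others to 0.459%), and normalised reads of 33.1 for MIR17, 9850 for MIR30D, 20100 for MIRLET7F and 93.7 for MIR29B-1 and MIR29B-2. In the same group sheep 132 had 2570 CPM of MIR133 among microRNA reads (others to 640), 459 for LOC114117093 (others to 64.5) and 464 for LOC114117060 (others to 76.1). In visceral controls of the T cohort, sheep 132 had an lncRNA share of 11.3%, a let-7 share of 55.8% and 1.66 for MIR323A. Sheep 098 had 2360 for MIR30D, 0.722 for LOC114117654 and 1.81 for LOC114115456. The other libraries were at 0 for these 2 loci. In such a case any value above 0 is flagged, and these flags are in the count of 31. Visceral fat of prenatal T sheep 255 had an lncRNA share of 5.99% (others from 11.4%).

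In subcutaneous controls of the T cohort, sheep 131 had 881 CPM of MIR133 among microRNA reads (others to 347) and 1.37 for LOC114118581, sheep 098 had 2.37 for LOC114115071, and sheep 132 had 3110 for MIR21 (others to 934). Sheep 201 had 17.3 for LOC114113420, 1.73 for LOC114109206, 4.18 for LOC105616014, 2040 for MIR10B, 244 for LOC105606646 and 6890 for MIRLET7F. For LOC114109206 the others were at 0, so that any value above 0 would be flagged. Subcutaneous fat of prenatal T sheep 255 had 4.05 for MIR369 and 37.3 for MIR362. Epicardial fat had 6750 for MIR23A in control 098 and 0 for LOC114117378 in prenatal T sheep 185. In visceral fat of the BPA cohort, control 902 had a snoRNA share of 2.55%, an snRNA share of 0.702%, 932 for MIR10B and 3230 for MIR26B, control 928 had 7.89 for LOC114110195 and 2.76 for LOC114109208, and BPA sheep 918 had a snoRNA share of 0.914% and 4.69 for LOC114115098. In subcutaneous controls of that cohort, 928 had 3.65 for LOC114118175 and 902 had 15.8 for LOC114113790.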

How the results depend on the processing

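The fits within 1 library set were chosen after seeing the data, and for comparisons of depots the median-ratio scaling was made the reported one after the deposited scaling had been found to be set within each depot. Of the counts and correlations under other settings 45 moved, and 28 without a sheep. Features under a mean of 5 were not tested, and the depth of 260804 to 1742991 reads per library sets which these are.

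Calls for prenatal T in subcutaneous fat (0) became 1 with a pseudocount of 5, 2 with CPM and 2 with edgeR. In visceral fat (0) they became 7 with the set term, 4 with edgeR, 6 with DESeq2 and 6 in 1 fit over all depots. In epicardial fat (3) they became 6 with a pseudocount of 5, 12 without a filter, 17 with DESeq2, and 0 with a mean of at least 20, the set term, adjustment over the 4 tables, edgeR, 1 fit over all depots, or the later set alone. In perirenal fat (0) DESeq2 gave 1. For BPA, calls in subcutaneous fat (0) became 2 without a filter and 3 with edgeR, and those in visceral fat (2) became 4 without a filter, 10 with CPM, 0 with the set term and 1 with adjustment over the 4 tables.

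For depots, subcutaneous calls (61) became 1.1e+02 (55 higher, 56 lower) with control and treated libraries together. Visceral calls (6) became 11 without a filter, 3 with CPM, 63 as deposited, 17 with the set term, 0 with adjustment over the 4 tables, 3 with edgeR and 27 with control and treated libraries. Epicardial calls (96) became 42 with the set term. Perirenal calls (48) became 110 as deposited, 93 with DESeq2 and 116 with control and treated libraries. Visceral against subcutaneous calls in the T cohort (31) became 52 as deposited, 47 with DESeq2, 61 with control and treated libraries and 12 in the early set alone. In the BPA cohort (37) they became 59 with CPM, 116 as deposited, 67 with the set term, 69 with DESeq2 and 93 with control and treated libraries.

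With sheep as a replicate block, visceral against subcutaneous calls in the T cohort became 59 and in the BPA cohort 52. The block gave 66 calls for subcutaneous, 9 for visceral, 115 for epicardial and 65 for perirenal fat, 0 for the prenatal T and 2 for the BPA effect by depot, all within 1.5 times of the count without it.

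Leaving out 1 sheep at a time gave 0 to 1 calls for prenatal T in subcutaneous, 0 to 0 in visceral, 0 to 8 in epicardial and 0 to 0 in perirenal fat, 0 to 5 for BPA in subcutaneous and 1 to 23 in visceral fat, 0 to 0 for the T and 2 to 3 for the BPA effect by depot. For depots it gave 28 to 45 in subcutaneous, 0 to 3 in visceral, 37 to 1.0e+02 in epicardial and 13 to 1.0e+02 in perirenal fat (the most without sheep 098, with 62 higher and 41 lower in epicardial and 47 and 56 in perirenal fat), and 4 to 28 (T) and 12 to 51 (BPA) for visceral against subcutaneous fat. The epicardial count was 43 without sheep 131, 37 without 132 and 53 without 201. The correlation of prenatal T and BPA effects ran from -0.409 to 0.046 in subcutaneous and from 0.146 to 0.592 in visceral fat. In subcutaneous fat it turned from -0.332 to 0.023 with the set term, 0.03 without control 201 of the T cohort and 0.046 without control 908 of the BPA cohort. In visceral fat it was 0.592 without prenatal T sheep 255. MIR127 in perirenal fat turned from -0.84 to 0.04 on the scaling as deposited.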

Other observations

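snoRNAs were also grouped by other genes they lie in, all chosen after seeing the data, and no group below that passed with fry passed with an estimated correlation. Of 6 snoRNAs in LOC114110053, 5 rose in epicardial fat, with a median of 1.66 (fry adjusted p = 0.0186, adjusted p = 0.268 with an estimated correlation), and in visceral against subcutaneous fat of the BPA cohort the 6 had a median of -1.99 (fry adjusted p = 0.0202, adjusted p = 0.26 with an estimated correlation, 0 called). Of 7 snoRNAs in TEX14, 1 fell in epicardial fat, with a median of -1.02 (fry adjusted p = 0.0681), and in perirenal fat their median was 1.27 (fry adjusted p = 0.0613). snoRNAs in ribosomal protein genes had 7 higher and 2 lower of 25 in epicardial fat (fry adjusted p = 0.0574) and 3 lower of 25 in perirenal fat (median -0.49, fry adjusted p = 0.0113, adjusted p = 0.42 with an estimated correlation). Of 9 in translation factor genes, 1 rose and 2 fell in epicardial fat (fry adjusted p = 0.0196, adjusted p = 0.268 with an estimated correlation) and 1 rose in subcutaneous fat (0.0483, adjusted p = 0.317 with an estimated correlation). With BPA in subcutaneous fat 0 of 10 were called, with a median of -0.28 (fry adjusted p = 0.0401, adjusted p = 0.15 with an estimated correlation).

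A hypothesis of shared regulation of the DLK1-DIO3 region was tested across the sheep of each depot. What it predicts was written down after the result had been seen. The mean log2 level of its microRNAs was compared with that of its snoRNAs and of the lncRNA LOC105606646, 12 relations in all, of which 9 passed after adjustment. The lncRNA spans the microRNAs and could hold their reads, so that only the snoRNAs were taken to decide. Of 6 relations with snoRNAs 4 passed, which shared regulation would give. snoRNAs from outside the region were not compared, so that a general covariation of the RNA classes between libraries could give this too. Each relation took control and treated sheep together. Those of the T cohort came from the same 8 sheep, so that they are not independent results. In perirenal fat r was 0.91 (rho 0.69, exact permutation p = 0.00198 and 0.0694, adjusted p = 0.0119, n = 8), 0.64 without the 2 farthest sheep and 0.92 among the 7 libraries of the early set. In epicardial fat r was 0.79 (rho 0.9, exact p = 0.018 and 0.00456, adjusted p = 0.027, n = 8), 0.62 without the 2 farthest and 0.94 among the 6 libraries of the later set.

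In visceral fat of the T cohort r was 0.82 (rho 0.62, exact p = 0.0162 and 0.115, adjusted p = 0.027, n = 8) and 0.45 without the 2 farthest sheep, so that it rests on them, and neither set held 6 libraries. In subcutaneous fat of the BPA cohort r was 0.75 (rho 0.76, exact p = 0.0279 and 0.0368, adjusted p = 0.0372, n = 8), 0.81 without the 2 farthest and 0.78 among the 7 libraries of the later set. The relation did not pass in visceral fat of the BPA cohort (r 0.15, rho 0.31, exact p = 0.737 and 0.462, n = 8) or in subcutaneous fat of the T cohort, where 1 snoRNA was measured (r 0.56, rho 0.81, exact p = 0.137 and 0.0218, n = 8). Cell types that differ in share between sheep, covariation of the RNA classes beyond this region, and a shift of both classes with treatment were not tested as explanations.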
